A study of Mus musculus with 6 samples.

How the data were processed

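Poly(A) mRNA of 6 whole mouse testes was measured by sequencing, 3 libraries labelled Stra8-deficient and 3 wild type. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, and libraries were made with an Illumina mRNA kit and sequenced on an Illumina flow cell. Per the submitters' processing notes, the authors used TopHat, HTSeq and edgeR with the mm9 genome build; versions, settings and the gene annotation are not given in the sources used here. The deposited counts are whole numbers of reads per gene symbol for each library, not normalised, followed by HTSeq's counters of reads outside genes. Strand handling is not stated, so reads of overlapping and antisense genes cannot be told apart, and reads of near-identical paralogs are uncertain. The deposited table of the authors' own comparison gives log2 ratios and log2 average abundances, and its deposited p-value columns hold the nominal and the false discovery rate corrected p per gene.

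The HTSeq counters name no gene and were left out of library sizes and tests. They took 20.9% to 34.5% of the reads of a library, most of it in reads outside annotated genes (20.2% to 29.2% of reads in the Stra8-deficient and 31.3% to 33.9% in the wild-type libraries). The file of the third Stra8-deficient library lists 23285 symbols and the other 5 files 22055 each, so it was counted on another gene list. All comparisons used the 21786 symbols present in all 6 files, which hold 99.3% to 99.7% of each library's gene reads. A further 1499 symbols occur only in the third Stra8-deficient file and 269 only in the other 5. Columns of samples that could not be matched to a label numbered 0. Depth was 6733128 to 12425689 gene reads per library. A total of 3 counts, taken as the limit that a count of 0 allows, amounts to 0.243 to 0.447 CPM per library before TMM scaling. Such limits and the counting intervals (95%, exact Poisson, and Wilson for shares of reads) cover counting error alone, since reads without molecular identifiers are not independent molecules.

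Genes were filtered with edgeR's filterByExpr, which kept 15018; 2848 symbols had 0 counts in all 6 libraries. Library sizes were scaled by TMM (factors 0.796 to 1.27) and genotypes compared with edgeR's quasi-likelihood F test (glmQLFit with robust estimation, edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment over the 15018 genes and a threshold of 0.05. Standard errors were derived as the size of the log2 fold change divided by the square root of its quasi-likelihood F. They are approximate, and for genes with few reads in a genotype they can fall below the counting error. Log2 CPM used a prior count of 2. The model has genotype as its one term, since age follows genotype in the labels. Before the data were examined, 23 gene lists (germ cell stages, somatic and immune cell types, blood, epididymis and pathways), the tests, the alternatives and a rule for the genes to be named were fixed. Lists with at least 3 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 and adjusted over 21 lists, again with an estimated correlation, and with fry. Fry's p tests whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction; neither compares the list with other genes. Fry called each of the 7 lists that camera called, in the same direction. With the estimated correlation none of the 7 lists that camera called remained called. For differentiating spermatogonia and mitotic genes that estimate was -0.036 and -0.023, below the preset value. Their lost calls therefore do not rest on a higher correlation among the genes. For the remaining called lists the estimate was 0.020 (pachytene), 0.039 (round spermatids), 0.177 (elongating spermatids), 0.238 (undifferentiated spermatogonia) and 0.724 (Sertoli cells). A call lost with the estimated correlation thus does not by itself show that a list's genes are highly correlated. The share of a library's gene counts held by each list was compared by exact two-sided permutation over the 3 and 3 libraries, for which the smallest possible p is 0.1.

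The named genes are Stra8; the 5 highest and 5 lowest log2 fold changes among called genes with an average log2 CPM of at least 4 and no overlap between genotypes; and for each list the 2 called members with the largest change in the main direction and the 1 with the largest change in the other direction, at an average log2 CPM of at least 0. Any member of the spermatogonial lists could be named in addition. A further 26 genes were chosen after their values were seen and are marked as such. Where a genotype had 0 reads of a gene, the fold is a bound computed against 3 counts over the 3 libraries of that genotype on the TMM scale; with 1 to 3 reads the ratio of rates is given with its counting interval.

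Gene symbols were matched to GENCODE M21 for chromosome, GC content and transcript length, by name for 19724 and through a RefSeq synonym for 1745 of the 21786 symbols (98.5%). That annotation is on another build than mm9, so it gave chromosome membership and gene order, and no coordinates are printed. No 2 libraries were duplicates: the chi-square per degree of freedom between counts was 2.74 to 4.40 among wild-type and 53.6 to 65.2 among Stra8-deficient pairs. On simulated counts for 3 against 3 libraries, with 200 of 15018 genes changed, the edgeR quasi-likelihood test recovered 24% of genes changed 2-fold and 73% of those changed 4-fold, and 5.82% of its calls were false. DESeq2 recovered 40% and 80% and the edgeR exact test 35% and 84%, with 20.5% and 21.7% false calls. A planted gene list was called by camera and 0 of 20 unchanged lists were. The simulated genes were independent and had the same spread in both genotypes. In the data 75.8% of genes were changed, and the biological coefficient of variation was 38.1% within Stra8-deficient and 7.41% within wild-type libraries. Estimated correlations within lists reached 0.856 (macrophages). The simulated rates therefore do not give the error rates of the real comparison.

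Alternatives were other scalings (DESeq2's RLE factors, library size alone, upper quartile, and the summed counts of the Sertoli cell list), no low-count filter or one of at least 1 CPM in all 3 libraries of a genotype, DESeq2 1.42.0, limma-voom, edgeR's exact test, thinning to the smallest library, leaving out each library, the replicate number as a block, a tested fold above 2, and lists without shared members. Offsets for a smooth trend on GC content and transcript length were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The value of 1 gene is not reported here.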

Results

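Polyadenylated RNA from whole mouse testes was sequenced in 6 libraries, and the number of reads falling in each gene was analysed. Per the labels, 3 libraries came from grossly enlarged testes of Stra8-deficient males aged 1 year and 3 from normal testes of wild-type males aged 2 to 4 months, all on a C57BL/6 background. Stra8 encodes a retinoic-acid-induced factor that germ cells need to enter meiosis, and the labels describe the enlarged testes as made up largely of cells that look like type A spermatogonia. The comparison asked how mRNA levels in such testes differ from those of normal adult testes. Age differed together with genotype, so the effects of genotype, age and testis enlargement cannot be separated. Reads in genes numbered 7883466, 8561174 and 12425689 in the Stra8-deficient libraries and 7910732, 8937224 and 6733128 in the wild-type libraries. The labels describe separate males, and p-values rest on the spread between these 3 and 3 testes. The fit shares its estimate of spread between the genotypes. The biological coefficient of variation was 27.3% for both together, 38.1% within Stra8-deficient and 7.41% within wild-type libraries. The shared estimate therefore matches neither genotype. Fold changes are log2, Stra8-deficient over wild type, with an approximate standard error (SE) derived from edgeR's F statistic. Levels are CPM, a gene's counts scaled to the library's total times its TMM factor, with the SD over 3 libraries. Shares of counts use the totals without these factors, which were 1.21 to 1.27 in Stra8-deficient and 0.796 to 0.813 in wild-type libraries.

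Stra8 itself, on chromosome 6, was read in every library of both genotypes. Its counts were 211, 249 and 270 in the Stra8-deficient libraries and 120, 132 and 93 in the wild-type libraries. On the normalised scale these were 21.2, 23.7 and 18.1 CPM against 18.7, 18.6 and 17.1 CPM. The log2 fold change was 0.21 ± 0.21 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.384). The counts sum all exons and the sources used here do not give the deleted part of the allele, so the level of Stra8 does not check the labels, and "Stra8-deficient" stands throughout for a library so labelled. Under library-size scaling without TMM the log2 fold change was 0.83 (edgeR, adjusted p = 0.00568), and under scaling to the Sertoli cell list it was 2.93 (edgeR, adjusted p = 1.06e-04). With offsets for GC content and transcript length, chosen after seeing the data, it was 0.69 (edgeR, adjusted p = 0.0178).

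Most of the measured transcriptome differed between the genotypes. Mmp12, a macrophage elastase, was read 1691 times in the Stra8-deficient libraries and 0 times in the wild-type libraries, at least 302-fold higher, or at least 157-fold without the third Stra8-deficient library. Genes were ranked by fitted value among called genes with an average log2 CPM of at least 4 and no overlap between genotypes. Pax7, below that level, had a fitted value of 10.10 over 0 wild-type reads. The other highest genes in this ranking included Phlda2, an imprinted gene known from placenta, at 9.39 ± 0.65. Gpnmb, a transmembrane glycoprotein of macrophages and melanocytes, was at 8.74 ± 0.56. Without the third wild-type library the value of Phlda2 was 10.44. Pgc, which encodes the protease precursor progastricsin, and Nphs1, which encodes nephrin, had a single wild-type read each, and their ratios were 855 (95% counting interval 153 to 33757) and 653 (95% counting interval 117 to 25809). Where a genotype had 0 reads the fit sets the fold, so such genes need not have changed most. Adam2, with 1 Stra8-deficient read, had a wild-type to Stra8-deficient ratio of 18733 (95% counting interval 3362 to 739900). This point ratio cannot be ranked against the bounds that follow, which assume 3 counts. Each of the 5 genes with those bounds had more wild-type reads (11968 to 20227) than Adam2 (10025). The 5 genes with the lowest fitted values in the same ranking had 0 reads in the Stra8-deficient libraries. They were 1700016M24Rik (at least 12599-fold lower), the spermatid linker histone gene H1fnt (at least 10675-fold lower), 1700009N14Rik (at least 8735-fold lower), 1700110M21Rik (at least 7969.6-fold lower) and Gykl1, a glycerol kinase-like gene of the testis (at least 7454-fold lower). Of 15018 genes tested, 11379 (75.8%) were changed, with 5860 higher and 5519 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The fold was at least 2 for 9727 of them, 4915 higher and 4812 lower, and 7937 passed a test against a fold of 2 (edgeR's glmTreat), 3826 higher and 4111 lower. In 12040 genes the 3 libraries of one genotype lay on one side of the 3 of the other, which chance gives for 10% of genes. The first principal component of log2 CPM separated the genotypes and held 93.8% of the variance. The split of directions depended on the scaling. Higher genes made up 51.5% of the calls with TMM, 48.9% with RLE size factors, 63.6% with library size alone, 57.3% with upper-quartile factors and 85.2% after scaling to the Sertoli cell list, so which direction held more genes turned with the scaling. The median log2 fold change of all genes was 0.11, -0.009, 0.73, 0.38 and 2.71 under these scalings, so each change is relative to that value.

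**Figure D1:**
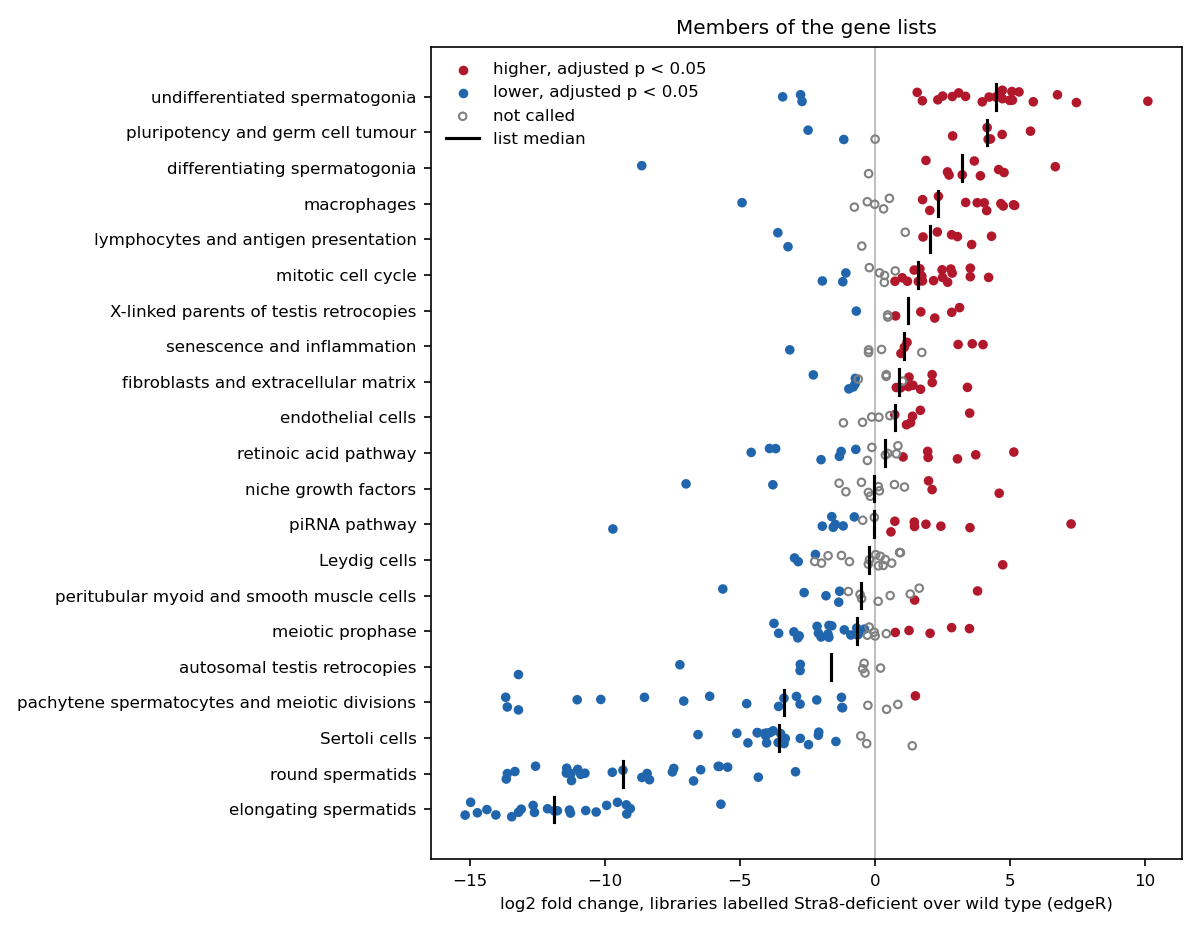
Log2 fold change (x axis, Stra8-deficient over wild type, edgeR) of each tested member of the 21 gene lists with at least 3 tested members (y axis, ordered by median). Each point is a gene, red where higher and blue where lower at an adjusted p under 0.05 and open where not called, and the black bar is the list's median. The 25 members of the round spermatid list and the 23 of the elongating spermatid list all lie below 0 (medians -9.33 and -11.88), and 22 of the 25 members of the undifferentiated spermatogonia list lie above 0 (median 4.47).

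Genes of haploid germ cells fell throughout. All 25 tested members of the round spermatid list and all 23 of the elongating spermatid list were lower, with the same counts adjusted over the list alone, and both medians stayed below 0 under every scaling. Among them, Prm2, a protamine that packs sperm DNA, was read 9 times in the Stra8-deficient libraries, all in the first, and 168512 times in the wild-type libraries (-14.97 ± 0.85; edgeR, adjusted p = 5.79e-07). Spata3, a testis-specific gene, had 0 Stra8-deficient reads and was at least 6047-fold lower, as was Catsper1, a sperm calcium channel subunit, at least 2095-fold lower. For Actl7a, an actin-like gene of spermatids, 1 read against 9953 gave a wild-type to Stra8-deficient ratio of 18598 (95% counting interval 3338 to 734590). The median log2 fold change was -9.33 for round and -11.88 for elongating spermatids, and -8.63 and -11.76 with the 3 members of each list that had 0 reads in one genotype set at their bound. The round spermatid list held 0.00622 ± 0.000672% of the counts in Stra8-deficient and 0.624 ± 0.0183% in wild-type testes (SD, n = 3 each). For the elongating spermatid list these shares were 0.0134 ± 0.00121% and 3.79 ± 0.21%. Both lists were lower in camera, limma's competitive gene set test (adjusted p = 2.03e-11 for each with a preset correlation), and neither was called with an estimated correlation (adjusted p = 0.102 for round and 0.124 for elongating spermatids). Exact two-sided permutation of a share between 3 and 3 libraries cannot go below p = 0.1, the value found for each list share given here apart from the plotted Leydig share (p = 1).

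The list of pachytene spermatocytes and meiotic divisions fell as well. Of its 21 tested members 17 were lower, 1 was higher and 3 were not called, with the same counts adjusted over the list alone. Adam3 and Adam2, sperm surface proteins first transcribed in spermatocytes, had 3 and 1 reads in the Stra8-deficient libraries, and the wild-type to Stra8-deficient ratios were 15375 (95% counting interval 5261 to 74557) and 18733 (95% counting interval 3362 to 739900). The exception was Cdc25c, a phosphatase that drives entry into M phase (1.49 ± 0.22; edgeR, adjusted p = 1.88e-04). The list's median was -3.37, and it held 0.186 ± 0.00944% of the counts against 1.37 ± 0.0236% in wild type (SD, n = 3 each). Camera called it lower (adjusted p = 5.84e-05), but not with an estimated correlation (adjusted p = 0.124).

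Genes of meiotic prophase did not move as one. Of 29 tested members 19 were lower, 5 higher and 5 not called, with the same counts adjusted over the list alone. Spo11, whose product makes the DNA breaks of meiotic recombination, fell by 3.74 ± 0.22 (edgeR, adjusted p = 5.13e-07), and Spata22, a recombination gene, was lower at -3.57 ± 0.62. Mei4, another gene needed for these breaks, rose by 3.49 ± 0.37. Among genes chosen after their values were seen, the meiotic cohesin gene Rec8 was lower (-2.86 ± 0.21) and Tex15, which acts in meiotic recombination and transposon silencing, was higher (2.04 ± 0.33). The synaptonemal complex gene Sycp1 (-0.03 ± 0.19; edgeR, adjusted p = 0.887) and the recombinase gene Dmc1 (0.00 ± 0.21; edgeR, adjusted p = 0.989) were not called. Sycp3, of the same complex, was lower at -0.39 ± 0.16 (edgeR, adjusted p = 0.0448), a value that changed sign to 0.47 with offsets for GC content and transcript length, chosen after seeing the data, and to 0.22 with library size alone, and that lost its call when any 1 wild-type library (-0.35 to -0.45) or the third Stra8-deficient library (-0.37) was left out. Sycp3 was also not called with upper-quartile factors (-0.12), without a low-count filter (-0.37) or in edgeR's exact test (-0.39), and was called higher after scaling to the Sertoli cell list (2.29). With library size alone Sycp1 (0.59) and Dmc1 (0.62) were called higher, as they were after scaling to the Sertoli cell list (2.67 and 2.57). Spo11, Spata22 and Rec8 were not called after scaling to the Sertoli cell list, and Spata22 was at -4.46 without the first Stra8-deficient library. The list's share of counts was 0.355 ± 0.0834% in Stra8-deficient and 0.278 ± 0.00747% in wild-type testes (SD, n = 3 each), while its median log2 fold change was -0.68 and became -0.07 with library size alone and 2.03 after scaling to the Sertoli cell list. The list was not called by camera (adjusted p = 0.0938, and adjusted p = 0.377 with an estimated correlation), while fry, limma's self-contained test of whether a list's genes move one way on balance, called it lower (adjusted p = 3.99e-04).

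Genes of the piRNA pathway, which silences transposons in germ cells, and the retrocopy pairs of the testis went both ways. In the piRNA list 8 of 17 members were higher, 7 lower and 2 not called. Piwil4, the nuclear Piwi protein of fetal and early postnatal germ cells, rose by 7.26 ± 0.35, from 0.594 ± 0.157 to 91.3 ± 23.2 CPM (edgeR, adjusted p = 1.66e-07), and Fkbp6 by 3.51 ± 0.32. Tdrd6, a chromatoid body component, fell by 9.70 ± 0.29. The germ cell helicase Ddx4, chosen after its value was seen, was lower at -1.55 ± 0.19, a value that changed sign to 1.17 after scaling to the Sertoli cell list. Of 8 X-linked genes with a testis retrocopy, 5 were higher, 1 lower and 2 not called, led by Pdha1, a pyruvate dehydrogenase subunit (3.13 ± 0.22), and the centrin gene Cetn2 (2.84 ± 0.20). Phf8, a histone demethylase, was lower (-0.69 ± 0.23; edgeR, adjusted p = 0.0213), which was not called with library size alone or upper-quartile factors and changed sign to 2.00 after scaling to the Sertoli cell list. Its call was also lost without the second Stra8-deficient library (-0.69) or any 1 of the wild-type libraries (-0.68 to -0.72). Of the 8 autosomal retrocopies 4 were lower and 4 not called, including Pgk2 (-13.20 ± 0.49) and Cetn1 (-7.23 ± 0.35) among the lower ones. Pgk2 was at -14.49 without the first Stra8-deficient library. Reads of such near-identical copies can be split between parent and copy by the counting, so these values are uncertain. Counts adjusted over the list alone were the same for all 3 lists. Camera called none of them (adjusted p = 0.911 for piRNA, 0.0559 for the X-linked and 0.0664 for the autosomal genes, and adjusted p = 0.932, 0.265 and 0.337 with an estimated correlation), while fry called the X-linked genes higher (adjusted p = 1.73e-05) and the autosomal genes lower (adjusted p = 5.58e-05). With the preset correlation the X-linked list was called without the second (adjusted p = 0.0478) or the third Stra8-deficient library (adjusted p = 0.0472) and the autosomal list without the second (adjusted p = 0.0478). For piRNA the median (-0.03) and mean (0.04) differed in sign, and so did fry (down, adjusted p = 0.0331) and camera (up). The piRNA median was above 0 with library size alone (0.59) and upper-quartile factors (0.25).

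Most genes on the lists of spermatogonia, the mitotic germ cells of the testis, were higher. In the list of undifferentiated spermatogonia 22 of 25 members were higher and 3 lower. Pax7, a marker of a rare stem-like spermatogonial population, had 545 reads against 0 in wild type and was at least 97.2-fold higher. Nanos3, an RNA-binding germ cell factor, rose by 7.45 ± 0.24, from 1.05 ± 0.114 to 187 ± 22.4 CPM (edgeR, adjusted p = 2.79e-08). The GDNF receptor gene Gfra1 rose by 4.99 ± 0.21 and the transcription factor gene Zbtb16 by 4.66 ± 0.32. The 3 lower members were Lhx1 (-3.42 ± 0.47), Id4 (-2.76 ± 0.21) and Etv5 (-2.70 ± 0.65), and none of the 3 was called after scaling to the Sertoli cell list. Lhx1 was at -4.04 without the second and Etv5 at -3.92 without the third Stra8-deficient library. The list took 0.349 ± 0.127% of the counts in Stra8-deficient and 0.0180 ± 0.000827% in wild-type testes (SD, n = 3 each), 19.4-fold more. In the list of differentiating spermatogonia 9 of 11 members were higher, 1 lower and 1 not called. Ccnd2, a D-type cyclin, rose by 6.67 ± 0.29 to 1575 ± 422 CPM, Crabp1, which binds retinoic acid, by 4.77 ± 0.25, the receptor gene Kit by 2.68 ± 0.23 and the transcription factor gene Sohlh1 by 4.57 ± 0.31. Dmrtb1, a transcription factor that acts at the switch from mitosis to meiosis, fell by 8.64 ± 0.36 (edgeR, adjusted p = 7.68e-08). This list held 0.465 ± 0.0521% against 0.0937 ± 0.00172% of the counts (SD, n = 3 each). Counts adjusted over the list alone were the same for both lists. Camera called both higher (adjusted p = 5.84e-05 and 0.00802), and neither with an estimated correlation (adjusted p = 0.346 and 0.145). Median log2 fold changes were 4.47 (also with Pax7 at its bound) and 3.23, and they stayed above 0 under every scaling.

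**Figure D2:**
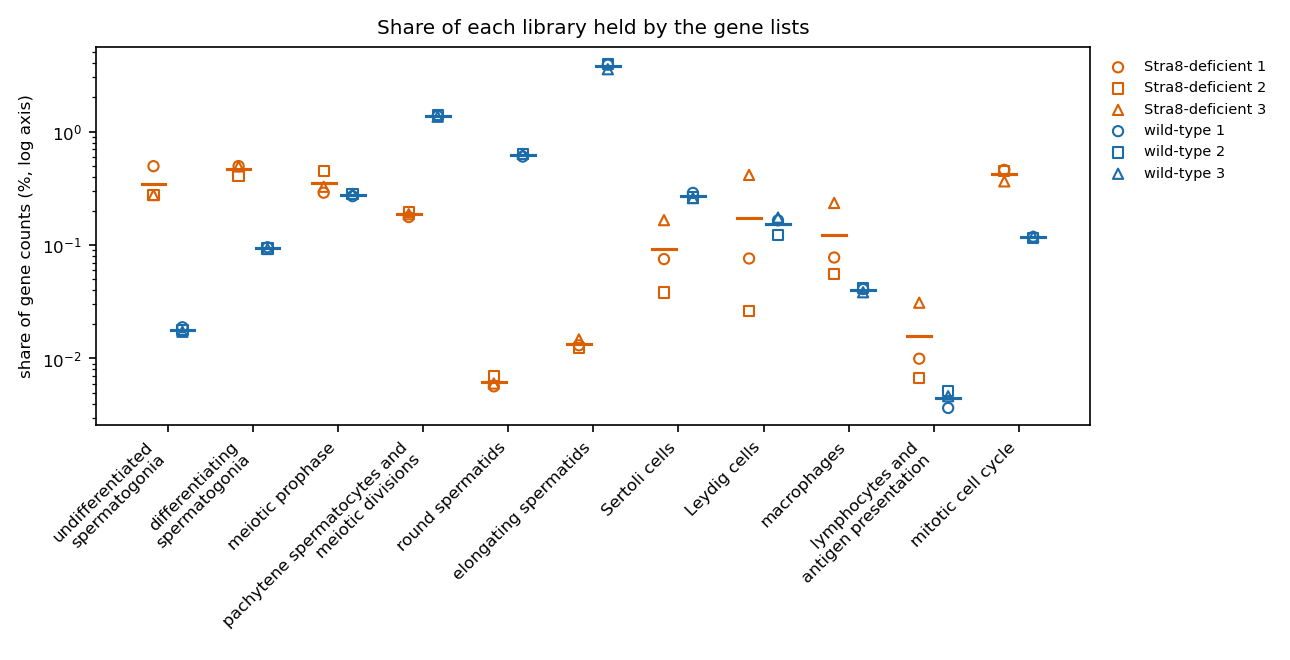
Share of each library's gene counts (y axis, percent, log axis) held by 11 gene lists (x axis), with one symbol per library (orange for Stra8-deficient, blue for wild type) and a bar at the mean of each genotype. Undifferentiated spermatogonia genes average 0.349% of counts in the Stra8-deficient and 0.0180% in the wild-type libraries, elongating spermatid genes 0.0134% and 3.79%, and the Leydig, Sertoli, macrophage and lymphocyte lists spread widely among the 3 Stra8-deficient libraries.

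Genes that make, carry and degrade retinoic acid, the signal that induces Stra8, moved in both directions. Of 19 tested members 6 were higher, 7 lower and 6 not called, or 6 higher and 6 lower adjusted over the list alone. Lrat, the retinol-storing enzyme, fell by 4.58 ± 0.36 (edgeR, adjusted p = 3.49e-06) and Cyp26b1, an enzyme that degrades retinoic acid, was lower at -3.91 ± 0.45, which was -4.72 without the first Stra8-deficient library and not called after scaling to the Sertoli cell list. Cyp26a1, a related enzyme chosen after its value was seen, rose by 3.73 ± 0.36, and Crabp2, a retinoic acid carrier with 2 wild-type reads, was higher with a ratio of 39.3 (95% counting interval 10.9 to 325). The list was not called by camera (adjusted p = 0.911, and adjusted p = 0.932 with an estimated correlation), and its median (0.38) and mean (0.08) lay above 0 while fry pointed down without a call (adjusted p = 0.423). The median was 0.12 without the first Stra8-deficient library, 0.11 with the GC and length offsets, 0.15 without a low-count filter and 1.003 with library size alone. Among 14 niche growth factors and receptors 3 were higher, 2 lower and 9 not called, with the same counts adjusted over the list alone. The lower members were Gfra2, a receptor of the GDNF family (-7.00 ± 0.35), and Gdnf, which maintains spermatogonial stem cells and was chosen after its value was seen (5 reads against 41; -3.78 ± 0.51; edgeR, adjusted p = 1.15e-04), which was not called after scaling to the Sertoli cell list. Fgf8 rose by 4.59 ± 0.36 and Fgf9 by 2.11 ± 0.50. Camera did not call this list (adjusted p = 0.998, and adjusted p = 0.999 with an estimated correlation), and its median (-0.03) and mean (-0.24) were below 0 while camera pointed up. The sign of this median did not hold, since it was 0.17 without the second Stra8-deficient library, 0.06 without the third wild-type library, 0.59 with library size alone and 0.24 with upper-quartile factors.

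Mitotic cell cycle genes were mostly higher. Of 25 members 17 were higher, 3 lower and 5 not called, with the same counts adjusted over the list alone. The replication licensing genes Mcm2 and Cdt1 rose by 4.2 ± 0.30 (edgeR, adjusted p = 2.19e-06) and 3.53 ± 0.49 (2.82 for Cdt1 without the first Stra8-deficient library), and Mcm4, chosen after its value was seen, by 3.53 ± 0.20. Plk1, a mitotic kinase gene, was lower at -1.95 ± 0.24, which changed sign to 0.60 without a call after scaling to the Sertoli cell list. The list held 0.424 ± 0.052% of the counts in Stra8-deficient and 0.118 ± 0.00131% in wild-type testes (SD, n = 3 each), its median was 1.60, and camera called it higher (adjusted p = 0.00438), but not with an estimated correlation (adjusted p = 0.124).

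Of 9 tested genes of the pluripotency and germ cell tumour list, 6 were higher, 2 lower and 1 not called. Dppa4 and Sox2, expressed in pluripotent cells, had 1 and 3 wild-type reads, with Stra8-deficient to wild-type ratios of 67.4 (95% counting interval 12.1 to 2663) and 28.4 (95% counting interval 9.71 to 138), and Klf4 was lower at -2.48 ± 0.31, which became 0.04 and lost its call after scaling to the Sertoli cell list. Despite a median of 4.15, the list's share of counts was 0.00914 ± 0.00202% in Stra8-deficient and 0.0151 ± 0.000435% in wild-type testes (SD, n = 3 each). The share mostly follows Klf4, at 29.7 ± 13.8 CPM in Stra8-deficient and 166 ± 7.53 CPM in wild-type testes. Mean levels of the other tested members were at most 12.5 CPM (Tcl1) in either genotype. Of 11 senescence and inflammation genes 6 were higher, 1 lower and 4 not called. Cdkn2a, which encodes cell cycle inhibitors, rose by 4.00 ± 0.21, from 6.63 ± 0.395 to 106 ± 16.6 CPM (edgeR, adjusted p = 2.88e-07), and the cytokine gene Il1b was lower at -3.16 ± 0.51, which was -3.85 without the third Stra8-deficient library and not called after scaling to the Sertoli cell list. Counts adjusted over the list alone were the same for both lists, and camera called neither (adjusted p = 0.0938 and 0.196, and adjusted p = 0.38 and 0.377 with an estimated correlation), while fry called both higher (adjusted p = 1.67e-04 and 3.58e-04).

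Sertoli cell genes, the somatic markers of the seminiferous tubules, were lower. Of 24 tested members 21 were lower and 3 not called, and adjusted over the list alone 21 were lower and 1 higher. The cystatin gene Cst9 fell by 6.55 ± 0.74 (edgeR, adjusted p = 8.26e-05) and Tsx was lower at -5.12 ± 0.61. Chosen after their values were seen, the FSH receptor gene Fshr (-4.71 ± 0.47) and the transcription factor gene Sox9 (-4.00 ± 0.30) were lower, and Wt1, another transcription factor of these cells, was not called (-0.31 ± 0.18; edgeR, adjusted p = 0.138). Without the third Stra8-deficient library Cst9 was at -7.64 and Tsx at -6.24, and Wt1 was called lower without the first (-0.44), with thinned counts (-0.44) and with the GC and length offsets (-0.49), and changed sign to 2.26 after scaling to the Sertoli cell list. The list's median was -3.54, its share of counts was 0.0931 ± 0.0657% against 0.27 ± 0.016% in wild type (SD, n = 3 each), and the medians within the Stra8-deficient libraries differed by up to 2.02 (log2). Without the third Stra8-deficient library the Sertoli share was 0.0567%. Camera called it lower (adjusted p = 4.04e-04), but not with an estimated correlation (adjusted p = 0.583).

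Other somatic lists went both ways. For Leydig cells, which make testosterone, 15 of 19 members were not called, 3 were lower and 1 higher. Klk1b21, a kallikrein with close paralogs whose reads are uncertain (-2.98 ± 0.86), and Gramd1b (-2.85 ± 0.26) were lower and Hsd11b1, a glucocorticoid-converting enzyme, was higher (4.73 ± 0.75; edgeR, adjusted p = 3.54e-04). Insl3 (0.94 ± 1.77) and Cyp17a1 (-1.24 ± 1.62), abundant Leydig cell genes chosen after their values were seen, had wide errors and were not called (edgeR, adjusted p = 0.649 and 0.511). The Leydig list's median was -0.21, and without the third Stra8-deficient library it was -2.24 and called by camera (adjusted p = 0.0436), with Cyp17a1 then lower at -4.73 (edgeR, adjusted p = 0.00678), Klk1b21 at -5.71 and Insl3 at -1.98 and not called. Hsd11b1 was at 3.77 without the second. The list's median was above 0 with library size (0.39), upper-quartile factors (0.05) and Sertoli scaling (1.82). Among 14 genes of peritubular myoid and smooth muscle cells 5 were lower, 2 higher and 7 not called (4 lower and 2 higher adjusted over the list alone), from the smooth muscle actin gene Actg2 (-5.64 ± 0.91) and Lmod1 (-2.63 ± 0.54) to the desmin gene Des (3.79 ± 0.31). Among 18 fibroblast and matrix genes 9 were higher, 5 lower and 4 not called, with the collagen gene Col1a1 (3.42 ± 0.21; edgeR, adjusted p = 8.00e-07) and Lum (2.12 ± 0.65) higher and Mfap5 lower (-2.29 ± 0.72). Without the third Stra8-deficient library Actg2 was at -7.64 and Mfap5 at -3.31, and Lum was not called without the second Stra8-deficient (1.35) or the second wild-type library (1.91). Klk1b21, Gramd1b, Lmod1 and Mfap5 were not called after scaling to the Sertoli cell list, nor was Klk1b21 with the GC and length offsets or Mfap5 with library size alone, while Insl3 was called higher under Sertoli scaling (2.39). Of 11 endothelial genes 6 were higher and 5 not called (3 higher adjusted over the list alone), led by Pecam1 (3.50 ± 0.34) and Egfl7 (1.68 ± 0.26). Counts adjusted over the list alone were otherwise the same, and camera called none of these 4 lists (adjusted p = 0.293, 0.63, 0.331 and 0.249, and adjusted p = 0.877, 0.932, 0.583 and 0.604 with an estimated correlation). Fry called the fibroblast (adjusted p = 0.0102) and endothelial lists higher (adjusted p = 0.0166) and not the Leydig (adjusted p = 0.239) or peritubular list (adjusted p = 0.61).

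Many macrophage genes were higher. Of 17 members 11 were higher, 1 lower and 5 not called, with the same counts adjusted over the list alone. Tyrobp, an immune signalling adaptor, rose by 5.17 ± 0.64 (edgeR, adjusted p = 8.24e-05), the lysozyme gene Lyz2 by 5.12 ± 0.58, and the complement gene C1qc, chosen after its value was seen, by 4.66 ± 0.68. Aif1, the remaining called member, was lower at -4.92 ± 0.82, and this gene is also read in wild-type testis at 336 ± 33.4 CPM. Of 10 genes of lymphocytes and antigen presentation 6 were higher, 2 lower and 2 not called, again the same adjusted over the list alone. The T cell gene Cd2 rose by 3.58 ± 0.51, Cd8a, with 1 wild-type read, was higher with a ratio of 24.6 (95% counting interval 4.42 to 972), and Cd3d was lower at -3.60 ± 0.84. Without the third Stra8-deficient library the values of Tyrobp, Lyz2 and C1qc were 4.29, 4.28 and 3.55, and those of Aif1 and Cd3d -6.23 and -6.41. The macrophage list held 0.123 ± 0.0978% of the counts against 0.0404 ± 0.00185% in wild type and the lymphocyte list 0.0159 ± 0.0132% against 0.0045 ± 0.000776% (SD, n = 3 each), and the medians within the Stra8-deficient libraries differed by up to 2.25 and 2.44 (log2). Without the third Stra8-deficient library these shares were 0.0666% and 0.00835%, so the fold over wild type went from 3.04 to 1.65 for macrophages and from 3.53 to 1.85 for lymphocytes. Camera called neither list (adjusted p = 0.0732 and 0.436, and adjusted p = 0.819 and 0.86 with an estimated correlation), nor did fry (adjusted p = 0.102 and 0.239). The macrophage list was called in some settings and not in others (adjusted p from 0.0178 to 0.172 over the alternatives with the preset correlation, the lowest without the second Stra8-deficient library). Blood cell and epididymis genes, with fewer than 3 tested members each, held 6.21e-04% and 3.58e-04% of the counts in Stra8-deficient and 0.00225% and 0.00311% in wild-type testes (means, n = 3 each), with 2.52e-04% for blood cells without the second Stra8-deficient library.

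Genes on the X chromosome, which is silenced in meiotic spermatocytes, were shifted upward. Of 538 tested X-linked genes 288 were higher, 143 lower and 107 not called, against 5520 higher and 5316 lower of 14329 autosomal genes. The median log2 fold change was 0.97 for X and 0.08 for the autosomes, a difference of 0.88. Camera called the X-linked set higher (p = 0.00362), but not with an estimated correlation (p = 0.155) nor after scaling to the Sertoli cell list (p = 0.129). Among autosomes the median was highest for chromosome 6 (0.70) and lowest for chromosome 13 (-0.58). Chromosomes were assigned by gene symbol from GENCODE M21, which uses another genome build than the files, so no coordinates are given.

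The 3 Stra8-deficient testes differed among themselves far more than the 3 wild-type testes. The biological coefficient of variation was 38.1% within the Stra8-deficient and 7.41% within the wild-type libraries, estimated by edgeR without a test. Leydig cell genes varied most of the 21 lists, with medians 4.72 (log2) apart between libraries, followed by lymphocyte (2.44), macrophage (2.25) and Sertoli (2.02) genes, whereas mitotic genes were 0.11 and differentiating spermatogonia genes 0.20 apart. Pearson correlations of log2 CPM across genes were 0.943 to 0.957 between Stra8-deficient and 0.987 to 0.991 between wild-type libraries, where genes are not independent replicates. In the first Stra8-deficient library, genes of chromosome 5 lay below their mean level in the other 2 libraries, with a median log2 difference of -0.51 ± 0.02 (SE over 590 genes) after removal of a trend on GC content and transcript length. For chromosome 12 the difference was -0.30 ± 0.02 (SE over 306 genes), with the second library above the mean of the 3 (0.190) and the third near it (0.027). These SEs come from resampling genes, which are not independent replicates. This examination by chromosome was chosen after seeing the data.

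**Figure D3:**
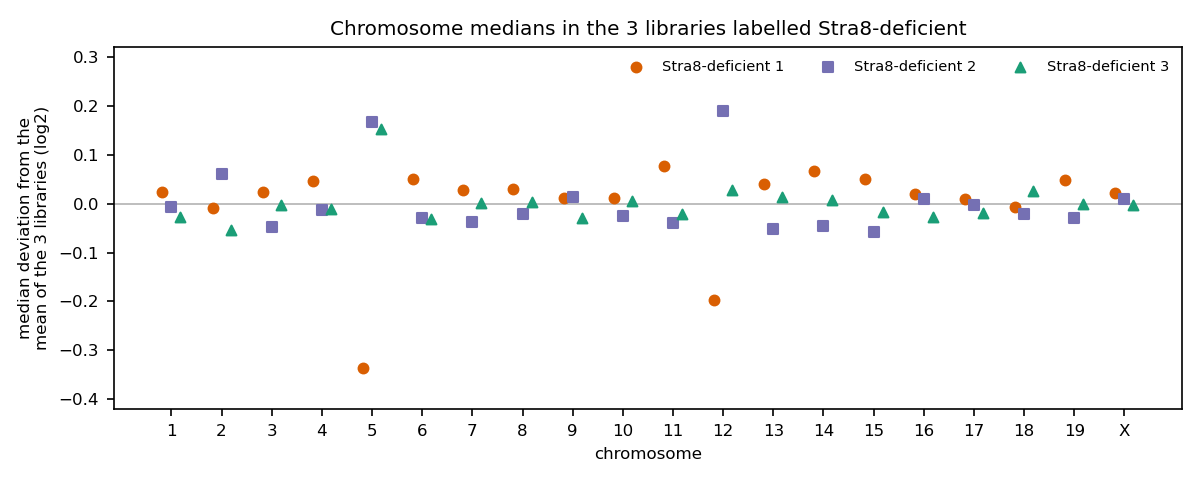
Median deviation of the genes of each chromosome (x axis) from the mean of the 3 Stra8-deficient libraries (y axis, log2, after removal of a trend on GC content and transcript length), with one symbol per library. The first library lies at -0.34 for chromosome 5 and -0.20 for chromosome 12, and at -0.01 or above for each other chromosome.

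The authors' deposited table of the same comparison was close to these values. It lists 19117 genes, of which 12624 have a corrected p under 0.05, 6434 higher and 6190 lower in Stra8-deficient testes. The authors' deposited table includes 181 genes that the file of the third Stra8-deficient library lacks. For Stra8 the authors' deposited table gives a log2 ratio of 0.21 with a corrected p of 0.585. Across the 15018 genes tested here, the log2 fold changes had a Spearman correlation of 0.9998 with those of the authors' deposited table and the same sign in 99.9% of genes, where genes are not independent replicates. Both called 10850 genes, all in the same direction, out of 11379 here and 11188 in the authors' deposited table. The libraries are the same ones, so this is a comparison of fits and not a second measurement.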

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

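The tests of chromosome 12, the tests of the other gene list, of copy number and of varying cell types, and the test of dilution were chosen after the results were seen; the remaining tests of GC content, gene clusters, random gene sets, Sertoli cell numbers and sample splits were set before their results were seen.

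Some reads lie outside the comparison. Of the 269 genes counted in the other 5 libraries alone, 114 were tested there, and 31 were higher and 56 lower in the Stra8-deficient libraries (edgeR, adjusted p under 0.05). Of 1499 symbols counted only in the third Stra8-deficient library, 493 had more than 3 reads. Reads set aside as ambiguous between genes made up 1.04% (95% Wilson interval 1.038 to 1.048%) of the third Stra8-deficient library, 0.723% (0.718 to 0.729%) of the first, 0.606% (0.602 to 0.611%) of the second and 0.646% (0.642 to 0.651%) of the highest wild-type library. These intervals cover counting error alone and not the spread between testes, and the third Stra8-deficient library was counted on another gene list, so no difference between genotypes is drawn from them.

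The count of changed genes, 11379 in the real grouping, was matched by 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, and the highest of the others gave 0 genes (edgeR). With 10 splits the share cannot fall under 0.05.

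In the first Stra8-deficient library, genes of chromosome 5 were lower than in the other 2 (-0.51 ± 0.02, SE over 590 genes, with 88.3% of genes below 0), a 1.42-fold difference. The SEs given for this chromosome come from resampling genes. Genes of a library are not independent replicates, so these SEs do not measure the spread between testes. A bias by GC content or transcript length is argued against, since the chromosome's median deviation was -0.337 after removal of that trend, where the lowest other autosome apart from 12 was at -0.01; so is a local gene cluster, since the weakest of 3 equal parts of the chromosome, in gene order, was at -0.458 ± 0.044 (SE). In a permutation test, 10000 random gene sets matched on level and direction reached at most 0.0855 in size (p = 1e-04, the smallest it can give). The sets were not matched on cell type, and the chromosome was picked for its shift. The test therefore does not decide whether a different mix of cell types contributed. The other gene list of the third library is argued against by the difference from the second library alone (-0.501 ± 0.025, SE). A difference between these testes in the copy number of chromosome 5, in part of their cells, may remain open as a hypothesis. The shift was alike in genes higher and lower in Stra8-deficient testes (difference -0.109 ± 0.0625, SE) and below 1 (log2) in size. Whether the first library was low or the other 2 were high cannot be told. Over wild type the median log2 fold change was 0.41 for chromosome 5 and 0.08 for the autosomes, but single autosomes ran from -0.58 to 0.70. RNA counts do not measure DNA copies, chromosome 12 moved the same way by -0.30, and a strain difference on these chromosomes was not tested.

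The spread between the Stra8-deficient libraries exceeded that of the wild type, with biological coefficients of variation of 38.1% and 7.41%. Trends on GC content and transcript length, which held 33.7%, 22.9% and 14.2% of the variance of the 3 Stra8-deficient libraries' deviations, are argued against as the whole cause, because the median gene-wise SD stayed 2.85 times that of the wild type after their removal (3.41 times before). The other gene list of the third library is argued against by the first and second alone, at 35.0%. Cell types in varying amounts may contribute: somatic and immune list genes had a median SD 2.84 times that of spermatogonial and mitotic list genes in the Stra8-deficient and 1.22 times in the wild-type libraries. These genes were filtered on their average level over both genotypes and not matched on level within a genotype, so the ratios can compare genes at unlike levels. Age, the degree of enlargement and the dissection of each testis stay open and were not tested.

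Sertoli cell genes were lower as a list (median -3.54; camera, adjusted p = 4.04e-04), but not called with an estimated correlation (0.724; camera, adjusted p = 0.583). Even dilution of every somatic cell type by germ cells, with expression unchanged, is argued against by 4 of 5 other somatic lists. Their medians lay more than 1 (log2) above the Sertoli median in each Stra8-deficient library. The smallest gaps were 1.75 for peritubular cells, 3.16 for fibroblasts, 3.46 for endothelial cells and 4.85 for macrophages, although a gain of macrophages alone stays open. List medians are not cell counts, and members went both ways for peritubular cells (2 higher, 5 lower) and fibroblasts (9 higher, 5 lower). Dilution together with lower expression in Sertoli cells was not tested. Leydig genes do not argue against even dilution, as their gap was 3.88 in the third library, 1.62 in the first and 0.19 in the second. Fewer Sertoli cells with unchanged expression and a change of expression within Sertoli cells cannot be told apart: 58.3% of the 24 members lay within 1 (log2) of the list's median, and a whole-testis library has no count of cells. Age, which followed genotype, stays open as well.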

How the results depend on the processing

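The GC content and transcript length offsets were chosen after seeing the data; the other settings were fixed before. Over the alternatives 10246 to 12303 genes were changed apart from 7937 in the test against a fold of 2, which had 3826 higher genes; leaving out a library gave 10246 to 11542. Reads outside the genes common to all files were not used, and lowly read genes limit folds to the bounds given. Scaling to the Sertoli cell list gave 10332 higher and 1800 lower genes and reversed 1012 calls, since those counts were themselves lower. Under it Stra8 was at 2.93, Plk1 at 0.60, Klf4 at 0.035, Phf8 at 2.00, Sycp3 at 2.29, Sycp1 at 2.67, Wt1 at 2.26, Ddx4 at 1.17 and Uhrf1 at 2.43, opposite in sign to the main values except for Stra8. The differentiating spermatogonia list (5.80) and the X chromosome (0.91) then lost their camera calls and the macrophage list (4.59) gained one. With library size alone Stra8 was called at 0.83, and Sycp3 (0.22) and Sycp1 (0.59) changed sign; with the GC and length offsets Stra8 was called at 0.69 and Sycp3 changed sign (0.47). With an estimated correlation camera called none of the lists at 4.47 (undifferentiated spermatogonia), 3.23 (differentiating spermatogonia), -3.37 (pachytene), -9.33 (round spermatids), -11.88 (elongating spermatids), -3.54 (Sertoli) and 1.60 (mitotic), nor the X chromosome (0.88). Lists that gained a camera call were macrophages without a low-count filter (2.21), with DESeq2 (2.22) and with the replicate block (2.15); the X-linked parents of retrocopies without the filter (1.60) and with thinned counts (1.15); and the autosomal retrocopies without the filter (-1.59), with DESeq2 (-1.73) and with the exact test (-1.61). Leaving out libraries, medians ranged from 1.63 to 2.58 for macrophages, from -2.24 to 0.29 for Leydig cells, from -1.21 to -0.20 for peritubular cells, from 0.50 to 0.94 for fibroblasts, from 1.17 to 1.27 for the X-linked parents and from -1.97 to -1.57 for the autosomal retrocopies. The median of the autosomal retrocopies (-1.61) was -0.43 with members of more than one list left out, -0.998 with library size alone and 0.83 after Sertoli scaling, without a call in any of these. The pluripotency median (4.15) was 1.63 without the low-count filter and the lymphocyte median (2.04) 0.89 without the third Stra8-deficient library. Without the 20 most abundant genes the difference in share was 0.176 for differentiating spermatogonia, -0.894 for pachytene, -0.649 for round and -1.75 percentage points for elongating spermatids. The replicate numbers do not pair the libraries: same-numbered deviations correlated at 0.058, 0.080 and -0.040, and the replicate block gave 11218 changed genes, with Sycp3 not called (-0.39). The cause of these differences was not tested, and 1763 other values of named genes kept their side of the threshold, 1737 of them with the same sign. The 26 with the other sign, in Dmc1, Igf2, Insl3, Sycp1, Uhrf1, Wt1 and Cyp17a1, were not called in either setting.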

Other observations

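These gene groups and the genes named here were chosen after their values were seen. Genes of the Y chromosome outside the lists were mostly higher in Stra8-deficient testes. Of 9 tested, 6 were higher, 1 lower and 2 not called, with a median log2 fold change of 1.63. Ube1y1, a ubiquitin-activating enzyme gene expressed in spermatogonia, rose by 3.77 ± 0.31 (edgeR, adjusted p = 5.11e-06), the histone demethylase gene Kdm5d by 3.04 ± 0.33 and Usp9y by 2.13 ± 0.30. On the X chromosome, Rhox10, a homeobox gene of spermatogonia, rose by 6.92 ± 0.41.

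Among single genes of DNA methylation and demethylation, which were not tested as a group, Dnmt3a, a de novo methyltransferase, rose by 2.54 ± 0.17 (edgeR, adjusted p = 1.44e-06), Dnmt1, which maintains methylation, by 1.57 ± 0.24, and Tet3, which oxidises methylcytosine, by 3.36 ± 0.22. Uhrf1, which recruits the maintenance enzyme to replicating DNA, was not called (-0.21 ± 0.29; edgeR, adjusted p = 0.529), and without the first Stra8-deficient library it was called lower at -0.64 (edgeR, adjusted p = 0.0131), and after scaling to the Sertoli cell list it was called higher at 2.43. The imprinted genes H19 and Dlk1 rose by 4.57 ± 0.37 and 4.89 ± 0.32, while Igf2, next to H19, was not called (0.06 ± 0.25; edgeR, adjusted p = 0.843), but was called higher with library size alone (0.68; edgeR, adjusted p = 0.0353) and after scaling to the Sertoli cell list (2.62; edgeR, adjusted p = 4.48e-04).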
